A study of Mus musculus with 35 samples.

How the data were processed

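The material was E14 mouse embryonic stem cells grown with serum, LIF and 2i. NELFA carrying a Strep-HA tag was induced with doxycycline, and formaldehyde-fixed, sonicated chromatin was precipitated with HA antibodies, per the labels' protocols. The 4 immunoprecipitated and 3 input libraries were represented by 1 deposited peak list, and libraries were not compared with one another. Trim Galore 0.4.2, Bowtie2 2.2.9, SAMtools 1.4, MACS2 and the mm10 build are named in the submitters' processing notes, without a version for MACS2. The settings of the peak call, how the libraries were combined, and how reads that align to several places were treated are not given in the sources used here. Every peak name in the list carries the tags R1234 and MAPQ0, whose meaning is not stated there either.

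The list has a narrowPeak layout with no header, and each interval appears once. Its fold enrichment column holds linear ratios, which the authors' peak caller gave for each peak. The deposited columns of significance hold the −log10 of a p-value and of a q-value. The lowest −log10 q was 1.31, which corresponds to a q-value limit of 0.05 in the deposited list. Summits were taken from the deposited offset from each interval's start. Fold enrichment was used only within the list, to describe, rank, filter and compare its peaks. The read depth is unknown, so no interval for a peak's fold could be given.

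Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49939 genes on chromosomes 1 to 19, X and Y, 21883 of them protein-coding. The table gives start, end and biotype without strand, exons or sequence. The tests fixed before the data were examined had named transcription start sites. In their place, a summit within 1 kb of either annotated boundary marked a gene as occupied, exons and introns were joined into the gene interior, and the position of summits was scored as inside or outside the gene within 500 bp of the nearest boundary. A boundary peak can therefore lie at a promoter or at a 3′ end. Tests that need sequence (CpG-rich promoters and motifs) were not run.

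Shares of summits and of neighbouring summits under 5 kb apart were compared with 1000 random placements of the same number of summits on each chromosome, within the span of its peaks and genes, by permutation p-values. Assembly gaps were not left out. Random summits placed in a gap count as between genes, which can raise the random share between genes and lower the random shares at boundaries and within genes. The strength of boundary peaks against the rest was compared as the mean log2 of fold enrichment with 100000 resamples. Gene lists, biotypes and chromosomes were compared by two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the 18 lists, and shares carry 95% Wilson intervals. The lists covered 2-cell-state genes and regulators, pluripotency, glycolysis, pausing machinery, histones, ribosomal proteins, proteasome, oxidative phosphorylation, immediate early, heat shock, unfolded protein response, lineage, trophoblast, fibroblast, olfactory, vomeronasal and differentiated-tissue genes.

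The rule for named genes, set before the data were examined, took for each list up to 4 members with the highest fold at a boundary and up to 3 without a boundary peak in alphabetical order, the 10 protein-coding genes with the strongest boundary peaks, the 5 strongest distal peaks, and always Nelfa, Dux, Duxf3, the Zscan4 genes, Zfp352, Dppa2, Dppa4 and Top2a. One item that this rule selects is not reported here.

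Alternatives set beforehand were windows of 500 bp and 2 kb, peaks at or above the median fold, peaks with a −log10 q of at least 4, overlap of the interval in place of the summit, −log10 q as the measure of strength, protein-coding and isolated genes for the side of the summit, and a spacing of 20 kb. Chosen after the data were seen were control windows 5 to 7 kb outside each gene, protein-coding boundaries for the shares of summits, peaks and genes outside 1 Mb windows with 30 or more peaks (called densely covered), the list without chromosomes 6 and 8, and 10000 random lists matched, in 10 bins, on the number of peaks 5 to 55 kb outside each gene.

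The procedure was tested on simulated data. When 2000 of the 21883 protein-coding genes received a summit near one boundary, 100% of them were found occupied. This only checks the code, since each planted summit lay inside the scored window. Uniformly placed summits gave a boundary share of 5.99%, within the range of 200 placements (5.98 to 6.46%). Of 200 lists of 30 genes with 21 planted members 100% were called, and 3% of random lists were called both by the Fisher exact test and against matched lists. The random lists drew single genes from the whole set, so these rates do not cover lists of neighbouring copies. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.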

Results

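The series examined NELFA, a subunit of the negative elongation factor complex that holds RNA polymerase II near promoters, in mouse embryonic stem cells, and its relation to the 2-cell-like state, in which a few cells of a culture express genes of the 2-cell embryo. It comprised 35 libraries, of which 7 were chromatin immunoprecipitation (ChIP-seq) libraries of E14 embryonic stem cells carrying a doxycycline-inducible NELFA with a Strep-HA tag. These cells had received doxycycline at 0.4 µg/ml for 16 h, and their chromatin was precipitated through the HA tag. There were 4 immunoprecipitated libraries from 3 replicates, 3 of them made with a first HA antibody and 1 with a second, and 3 input libraries. The 20 RNA-seq and 8 ATAC-seq libraries were not analysed here. The ChIP-seq values were read from 1 peak list with no column for a single library. It carries no value per replicate and no read depth, the peak values have no replicate error, and peaks and genes are not replicates of the experiment. The p-values describe this list, and the intervals cover counting error only.

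The list held 59485 peaks, 58625 of them on chromosomes 1 to 19, X and Y of the mm10 mouse assembly. Most were weak and narrow. The median fold enrichment, as the authors' peak caller gave it, was 2.09 and the median width 170 bp. A fold enrichment under 3 was given to 85.8% of the peaks, 1784 peaks (3%) had a fold of at least 5, and 139 reached 10. The strongest was 27.3. The design text names the comparison of cells with high and low NELFA, and the ChIP-seq bears on where the tagged protein lay along the genome, including at genes of the 2-cell-like state.

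Peaks of the HA-tagged NELFA lay at the ends of genes more often than random placement gives. Among the gene groups examined, histone, heat shock and ribosomal protein genes most often had a peak there. Every ChIP library came from induced cells, with input as the only control. HA signal that does not depend on the tagged protein therefore cannot be separated in the list. The coordinates used gave the start and end of each gene but not its strand, so a gene counted as occupied when a summit lay within 1 kb of either boundary, which can be its promoter or its 3′ end. Of the 58625 summits, 8044 (13.7%) lay within 1 kb of a boundary of any annotated gene, against a mean of 6.24% (range 5.91 to 6.55%) over 1000 random placements on the same chromosomes, a 2.2-fold excess (one-sided permutation p = 0.001, the smallest these placements can give). Summits inside genes but farther from a boundary made up 38.1%, below the 43.8% of the placements, and summits between genes 48.2%, below 49.9% (two-sided permutation p = 0.002 for each, the smallest possible). The shortfall between genes was not found without chromosomes 6 and 8 (50.3%, permutation p = 0.837). It turned to an excess outside densely covered windows (55.9% against 51.2%) and when only protein-coding genes were counted (61.5% against 59.5%; two-sided permutation p = 0.002 for each).

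The excess was highest close to the boundaries of protein-coding genes. Within 100 bp of one, 1209 summits were found against 187 in random placements, a ratio of 6.47, and the ratio was 5.47 from 100 to 250 bp, 2.6 from 250 to 500 bp and 1.59 from 500 to 1000 bp. Farther out it stayed above 1, at 1.29 from 1 to 2 kb, 1.23 from 2 to 5 kb, 1.37 from 5 to 10 kb and 1.2 from 10 to 50 kb. Outside densely covered windows it was 10.2 within 100 bp and 0.678, 0.71, 0.946 and 1.02 at these 4 farther distances. Summits within 500 bp of a boundary of any gene lay on the gene's side of it in 3499 of 5555 cases (63%; two-sided exact binomial p = 2.47e-84), where random placements gave 47.1% (range 43.5 to 50.6%). With protein-coding boundaries only, the share was 72.7% (2790 of 3838). Near isolated protein-coding genes, which had no other boundary within 1 kb, it was 72.5% (1577 of 2175). Peaks near a boundary were stronger than the others by 0.07 on the log2 scale of fold enrichment, a ratio of 1.05 (two-sided permutation p = 2e-05, the smallest 100000 resamples can give). Outside densely covered windows the difference was 0.01 (permutation p = 0.135).

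**Figure D1:**
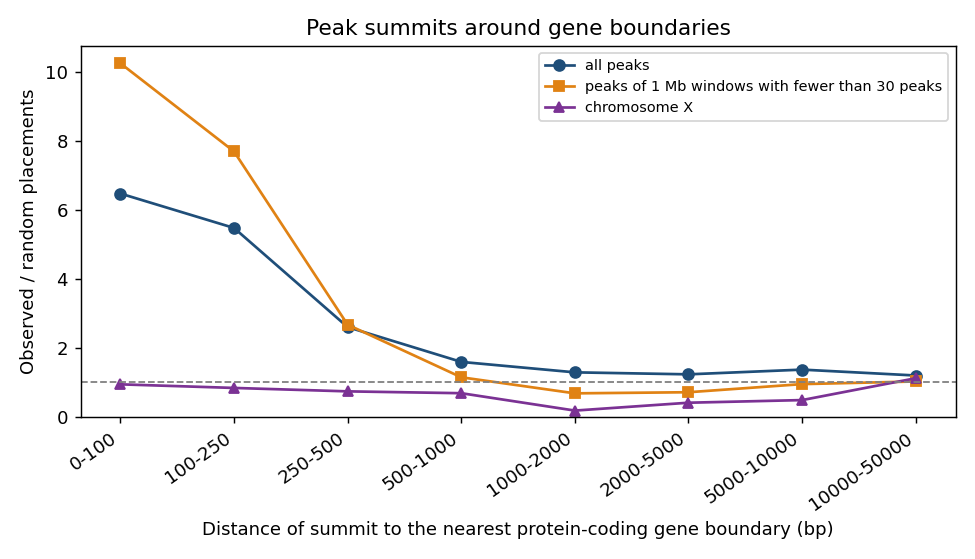
Ratio of observed summits to the mean of random placements (vertical axis) by distance to the nearest boundary of a protein-coding gene in bp (horizontal axis), for all peaks, for peaks of 1 Mb windows with fewer than 30 peaks and for chromosome X; the dashed line marks a ratio of 1. The ratio for all peaks falls from 6.47 within 100 bp to 1.59 at 500 to 1000 bp, while chromosome X stays at 0.939 within 100 bp.

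Among 21883 protein-coding genes, 4120 (18.8%) were occupied. In control windows of the same size, placed 5 to 7 kb outside the same genes, 8.6% had a summit. The strongest boundary peaks of the whole list were a mixture. The first was at Snrnp70, which encodes a protein of the U1 spliceosomal particle (chromosome 7, 45376454 to 45395742), with a fold of 11.1 and its summit 119 bp outside the gene. Lars2, the mitochondrial leucyl-tRNA synthetase, followed with 11.1 at 657 bp inside its higher-coordinate end. Its −log10 q was 1408, against 160 at Snrnp70 with nearly the same fold. Peaks in regions of unusually high signal were not left out here. The histone genes H2ac24 and H4c18 shared a single interval of fold 10.8 on chromosome 13 (21831495 to 21834430). The other 6 of the top 10 were the vomeronasal receptor gene Vmn2r29 (10.1) and the gene models Gm52481 on chromosome Y (10.03), Gm5662 (9.76), Gm7697 (9.05) and Gm8108 (8.71), with Speer4e (8.85). These 6 lay in 1 Mb windows holding 87 to 870 peaks.

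Of 18 gene lists fixed before the data were examined, 9 were occupied more often than the other protein-coding genes, 2 less often, and 7 did not pass the test (two-sided Fisher exact test with Benjamini-Hochberg adjustment over the lists). Lists matched on the number of peaks surrounding each gene, an alternative chosen after the data were seen, also gave 9 above and 2 below.

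Genes of the 2-cell-like state were occupied in 22 of 34 cases (64.7%, 95% Wilson interval 47.9 to 78.5%), against 18.8% of other protein-coding genes (odds ratio 7.94, adjusted Fisher exact p = 1.97e-08). Duxf3, a copy of the double-homeobox activator of the 2-cell programme, had the strongest boundary peak of the list. It lies on chromosome 10 from 58229505 to 58233089, and its peak at 58229613 to 58230555 had a fold of 7.6. Together with its neighbours it formed a block of 8 peaks from 58220890 to 58239760 with folds of 4.5 to 7.6, and the 9 other peaks within 25 kb had folds of 1.86 to 2.18. Gm4027 (6.4), Sp110 (5.17) and Gm2022 (4.08) followed. The Zscan4 genes, zinc-finger genes that mark the state, sit in tandem on chromosome 7. Their highest boundary folds were 2.95 at Zscan4b, 3.36 at Zscan4c, 3.45 at Zscan4d and 3.54 at Zscan4f. Zscan4a (2.68) and Zscan4e (3.54) are annotated as pseudogenes and were not counted in the list. Zfp352, a further marker (chromosome 4, 90218820 to 90225687), had 1 peak of fold 3.09 with its summit 142 bp outside the gene. Arg2, Obox1 and Obox3 were among the 12 without a boundary peak, although Obox3 had 1 peak of fold 4.13 in its interior. The symbol Dux is not used in the annotation. Surrounding peaks were frequent for this list: 14 of the 34 genes (41.2%) had a summit in the control windows, and matched lists were occupied in 45.9% (95% of lists between 32.4 and 58.8%; adjusted permutation p = 0.0277 from 10000 lists). Outside windows of 30 or more peaks, 5 of the 11 remaining members were occupied against 13.5% of other genes (adjusted Fisher exact p = 0.0194). These were Zfp352 and Tmem92, and from repeated gene families Duxf3, Usp17lc and Usp17le. The tests count copies in such families as separate genes.

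Regulators of the 2-cell-like state were occupied in 14 of 30 cases (46.7%, 30.2 to 63.9%; odds ratio 3.78, adjusted Fisher exact p = 0.000945), with 6.67% in the control windows. Trim28, the co-repressor of endogenous retroviruses, had a fold of 4.77, the nucleolar protein gene Ncl 3.49, the histone methyltransferase gene Setdb1 2.81 and Zmym2 2.68. Top2a, which encodes a DNA topoisomerase, had 1 peak of fold 2.0 at chromosome 11, 99024064 to 99024186, with its summit 51 bp inside the gene's higher-coordinate end. Dppa2 and Dppa4, neighbouring genes on chromosome 16 whose products activate Dux, had no peak at a boundary or in the gene. Atrx, Chaf1a and Chaf1b had none either.

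The pausing machinery, the list that holds the subunits of NELF and its partners, was occupied in 13 of 26 cases (50%, 32.1 to 67.9%; odds ratio 4.32, adjusted Fisher exact p = 0.000726), with 7.69% in the control windows. Nelfa is counted among the occupied genes, although reads from the NELFA transgene cannot be separated from those of the native gene. Polr2a, the gene of the largest subunit of RNA polymerase II, had a fold of 7.99 with its summit 39 bp inside the gene (chromosome 11, 69733997 to 69758633). Hexim1, an inhibitor of the elongation kinase P-TEFb, had 3.31 and Ccnt2, a cyclin of that kinase, 2.59. Aff1, Cdc73 and Ell2 had no boundary peak. With peaks of −log10 q of at least 4 only, the share was 23.1% against 9.8% of other genes (odds ratio 2.76, adjusted Fisher exact p = 0.0508).

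Nelfa itself (chromosome 5, 33897916 to 33936301) carried 13 peaks, where the 2560 other protein-coding genes of 30 to 50 kb had a median of 0. A peak of fold 7.76 lay at its higher-coordinate end, with the summit 147 bp inside. A run of 16 peaks under 2 kb apart reached from 33892044 to 33914797, over the lower-coordinate part of the gene and beyond its end, with folds of 1.91 to 17.2. Peaks covered 70.1% of this run, and 6 lay in the 10 kb beyond the gene's lower-coordinate end. The induced NELFA comes from an added transgene, so reads from this construct and from the native gene cannot be separated in the list.

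**Figure D2:**
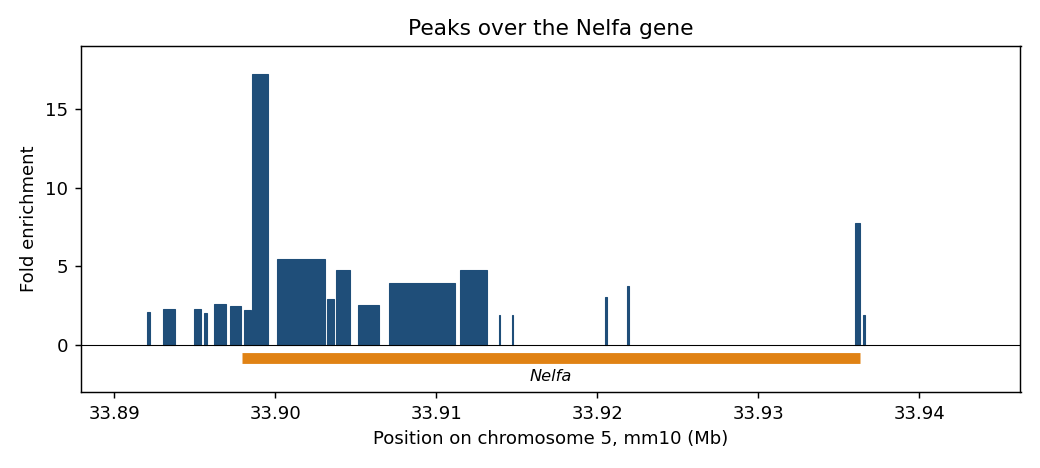
Peaks (bars, width to scale) by position on chromosome 5 in Mb of mm10 (horizontal axis) and fold enrichment (vertical axis); the orange line is the annotated Nelfa gene. The highest bar, 17.2, stands near the lower-coordinate end, the run extends beyond that end, and a separate peak of 7.76 marks the other end.

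Among the 18 lists, histone, heat shock and ribosomal protein genes had the highest shares. Heat shock genes were occupied in 15 of 17 cases (88.2%, 65.7 to 96.7%; odds ratio 32.5, adjusted Fisher exact p = 5.39e-09). The chaperone genes Hsp90aa1 (fold 8.53), Hspd1 and Hspe1, which share 1 peak between them (6.26), and Hspa8 (5.36) led, and Bag3 and Hsf2 were the 2 without. Ribosomal protein genes were occupied in 70 of 84 cases (83.3%, 73.9 to 89.8%; odds ratio 21.9, adjusted Fisher exact p = 1.2e-36), with 2.38% in the control windows. Rpl3 and Rps20 each had a fold of 5.26, Rps12 4.63 and Rpl36 4.27. Of the 14 without a boundary peak, 4 had a peak in their interior, Rpl17 and Rpl18 among them, and Rpl10l had none. Genes of the unfolded protein response were occupied in 12 of 18 cases (66.7%, 43.7 to 83.7%; odds ratio 8.65, adjusted Fisher exact p = 3.49e-05), led by the endoplasmic reticulum chaperone gene Calr (4.45), the stress transcription factor gene Atf4 (3.95), the asparagine synthetase gene Asns (3.72) and Ddit3 (3.13). Atf6, Dnajc3 and Edem1 had no boundary peak. Histone genes were occupied in 59 of 63 cases (93.7%, 84.8 to 97.5%; odds ratio 64.5, adjusted Fisher exact p = 2.78e-37). They stand in clusters, their control windows held a summit in 52.4%, and no member lay outside the densely covered windows. Several neighbouring members were occupied through the same peak, as H2ac21, H2ac20 and H2bc21 were on chromosome 3. The interval and p-value count such genes separately and so overstate the evidence. After H2ac24 and H4c18, H4c12 (6.58) and H4c9 (6.08) had the highest folds, and H1f6, H2ac1 and H2bc1 were among the 4 without a boundary peak.

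Pluripotency genes were occupied in 10 of 26 cases (38.5%, 22.4 to 57.5%; odds ratio 2.7, adjusted Fisher exact p = 0.0324). The transcription factor genes Klf2 (fold 3.54), Klf4 (3.13), Tfcp2l1 (2.54) and Nanog (2.5) led, and Dppa5a, Esrrb and Gbx2 were among those without a boundary peak. The call was lost without chromosomes 6 and 8, which hold Nanog and Klf2 (27.3% against 15.4% of other genes, odds ratio 2.07, adjusted Fisher exact p = 0.173), and with a window of 2 kb (odds ratio 2.25, adjusted Fisher exact p = 0.0808). It was also lost outside densely covered windows, where the odds ratio was 2.74 (30% against 13.5%, adjusted Fisher exact p = 0.0677). Oxidative phosphorylation genes were occupied in 25 of 79 cases (31.6%, 22.4 to 42.5%; odds ratio 2, adjusted Fisher exact p = 0.0104), led by Ndufa13 (5.58), Atp5a1 (3.59), Ndufb6 (3.22) and Atp5g2 (3.13). Atp5d, Atp5e and Atp5g1 had none. That call was lost with peaks at or above the median fold (20.3% against 12.4% of other genes, odds ratio 1.79, adjusted Fisher exact p = 0.0562) and with a −log10 q of at least 4 (17.7% against 9.78%, odds ratio 1.99, adjusted Fisher exact p = 0.0507).

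The other 7 lists, of metabolic, signalling, lineage and tissue genes, did not pass the test in the main setting. Glycolysis genes were occupied in 8 of 20 cases (40%, adjusted Fisher exact p = 0.0574), with folds of 4.99 at Gapdh, 3.81 at Pkm, 3.77 at Pgam1 and 2.31 at Eno1. Aldoa, Aldoc and Eno2 had no boundary peak. Of the 12 without one, 6 had a peak in their interior, Aldoa (2.63) and Eno2 (1.86) among them. This list passed with a 2 kb window (50%, adjusted Fisher exact p = 0.00897), at or above the median fold (30%, adjusted Fisher exact p = 0.0457), at a −log10 q of at least 4 (30%, adjusted Fisher exact p = 0.0205) and outside densely covered windows (38.5%, adjusted Fisher exact p = 0.0386), but not against matched lists (adjusted permutation p = 0.178). Immediate early genes were occupied in 7 of 19 cases (36.8%, adjusted Fisher exact p = 0.0898), led by Ier2 (4.77), Dusp1 (3.04), Btg2 (3.0) and Junb (2.59), with none at Ccn1, Egr1 or Egr2. They passed only with a 500 bp window (36.8%, odds ratio 3.04, adjusted Fisher exact p = 0.0356) and at or above the median fold (31.6%, odds ratio 3.25, adjusted Fisher exact p = 0.0427). Without chromosomes 6 and 8 they did not (25%, odds ratio 1.84, adjusted Fisher exact p = 0.309), and Ier2 and Junb lie on chromosome 8. Nor did they outside densely covered windows (28.6%, adjusted Fisher exact p = 0.124) or against matched lists (adjusted permutation p = 0.198). Proteasome genes were occupied in 10 of 39 cases (25.6%, adjusted Fisher exact p = 0.341), with 2.68 at Psmd5, 2.63 at Psmd7, 2.22 at Psmd11 and 2.18 at Psmc5, and none at Psma1, Psma3 or Psma5. With a −log10 q of at least 4 their odds ratio turned from 1.49 to 0.766 (adjusted Fisher exact p = 1). Lineage transcription factor genes were occupied in 3 of 26 cases (11.5%, adjusted Fisher exact p = 0.483). These were Sox1 (2.31), Hand2 (2.04) and Gata2 (1.82), all on chromosomes 6 and 8, and Cdx2, Dlx5 and Foxa2 had no boundary peak. With a 2 kb window their odds ratio turned from 0.562 to 1.08 (adjusted Fisher exact p = 0.814). No trophoblast marker was occupied (0 of 13, Wilson upper bound 22.8%, adjusted Fisher exact p = 0.176), Ascl2, Cdx2 and Elf5 included. Of 14 fibroblast markers, only Fn1 was (2.09; adjusted Fisher exact p = 0.491), and Acta2, Col1a1 and Col1a2 were not. Genes of differentiated tissues were occupied in 1 of 25 cases (4%, adjusted Fisher exact p = 0.0898), and Actc1, Alb and Apoa1 were among those without a boundary peak.

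Chemosensory receptor genes, which form large silent clusters in most tissues, were the 2 lists occupied less often. Of 1106 olfactory receptor genes 16 were occupied (1.45%, 0.892 to 2.34%; odds ratio 0.0596, adjusted Fisher exact p = 9.44e-77), none above the fold of 2.68 at Olfr108. Olfr209 (2.54), Olfr482 (2.5) and Olfr270 (2.45) followed, and Olfr1, Olfr10 and Olfr100 were among those without. Of 353 vomeronasal receptor genes 38 were occupied (10.8%, 7.94 to 14.4%; odds ratio 0.516, adjusted Fisher exact p = 0.00012). After Vmn2r29, the highest folds were at Vmn1r2 (4.86), Vmn2r43 (4.31) and Vmn2r32 (3.86), and Vmn1r1, Vmn1r10 and Vmn1r100 had none.

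**Figure D3:**
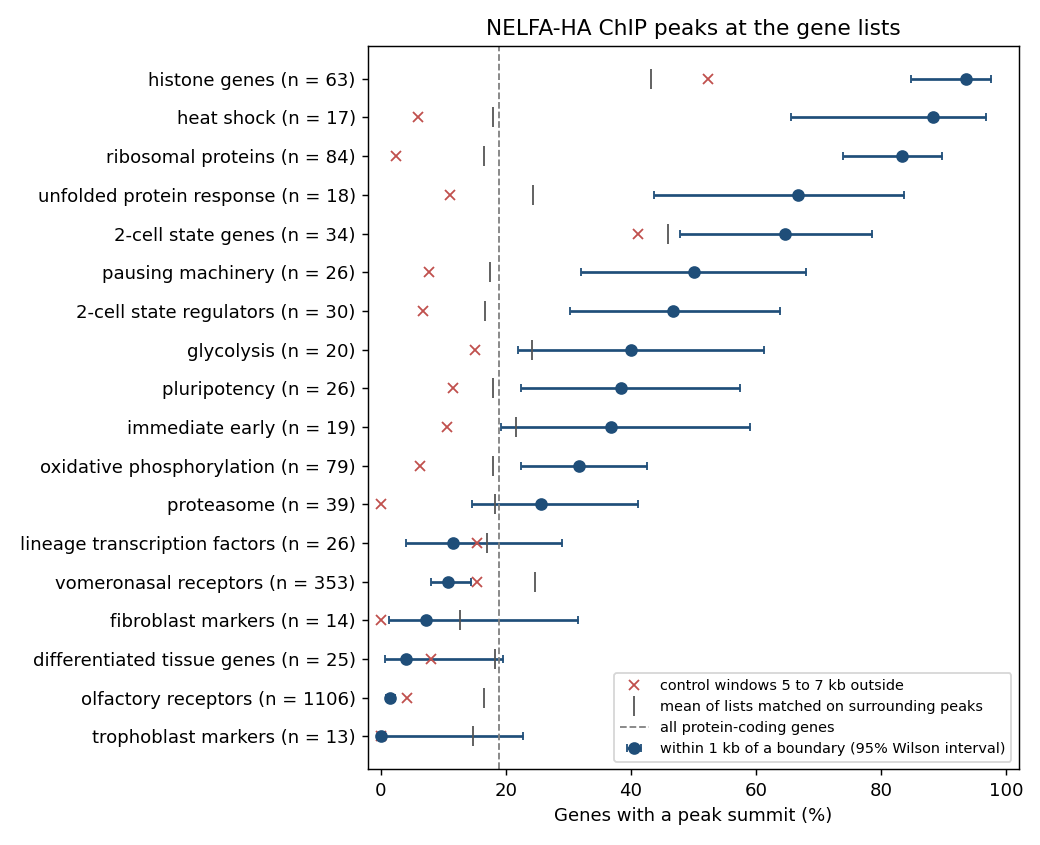
Percentage of genes of each list (rows, with the number of members) that have a summit within 1 kb of a boundary (points, bars are 95% Wilson intervals), in control windows 5 to 7 kb outside the same genes (crosses) and in lists matched on surrounding peaks (ticks); the dashed line is the 18.8% of all protein-coding genes. Ribosomal protein genes stand at 83.3% against 2.38% in their control windows, and histone genes at 93.7% against 52.4%.

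Long non-coding RNA genes were occupied less often than protein-coding genes, in 999 of 12727 cases (7.85%, 95% Wilson interval 7.39 to 8.33%) against 18.8% (18.3 to 19.4%; two-sided Fisher exact p = 1.98e-183), and their control windows held a summit in 6.43%. Annotated pseudogenes were occupied in 6.93% (control windows 9.38%), small nucleolar RNA genes in 13.4% (16.3%) and transfer RNA genes in 19.1% (21.6%). Ribosomal RNA genes were occupied in 34 of 63 cases (54%, 41.8 to 65.7%), with 66.7% in their control windows.

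Genes of chromosome X were almost free of peaks at their boundaries. Of 966 protein-coding genes, 21 were occupied (2.17%, 1.43 to 3.3%), against 4098 of 20661 autosomal genes (19.8%; odds ratio 0.0898, two-sided Fisher exact p = 4.55e-61). Chromosomes 6 and 8 stood at the other extreme, with 43% (40.1 to 45.9%) and 58.2% (55.1 to 61.1%) of their genes occupied, and the other 17 autosomes ranged from 11.3 to 22.5%. On chromosome Y, which held 3.31 peaks per Mb, 1 of 256 genes was occupied (0.391%, 0.069 to 2.18%). The control windows went the same way, with 1.24% on X, 26.6% on chromosome 6, 35% on chromosome 8 and 6.48% on the other autosomes together. Without chromosomes 6 and 8, the autosomal share was 16.3% (Fisher exact p = 2.36e-45). Away from genes, X stood closer to the autosomes. Over 10 kb from any protein-coding boundary it held 9.76 peaks per Mb, against 12.8 on the other 17 autosomes together. The read depth of each chromosome is unknown, so fewer called peaks on X need not mean less binding.

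**Figure D4:**
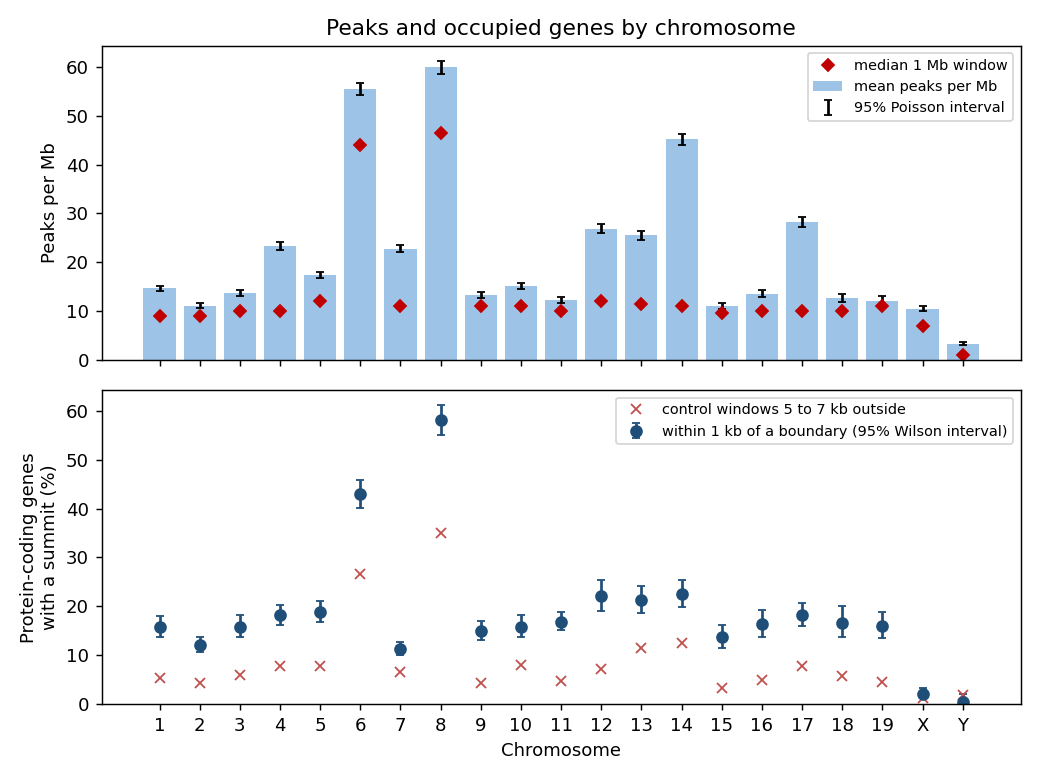
Upper panel: peaks per Mb of each chromosome (bars, with 95% Poisson intervals) and peaks in its median 1 Mb window (diamonds). Lower panel: percentage of protein-coding genes with a summit within 1 kb of a boundary (points, 95% Wilson intervals) and in control windows (crosses); chromosomes 6 and 8 stand above the others in both panels, with median windows of 44 and 46.5 peaks, and chromosome 14 has a high mean of 45.2 but a median of 11.

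Peaks were clustered. Of neighbouring summits, 58.5% lay under 5 kb apart, against 14.3% (range 13.9 to 14.7%) in random placements, a 4.09-fold excess (one-sided permutation p = 0.001, the smallest possible). Of 2714 windows of 1 Mb, 358 held 30 or more peaks and 58.1% of all peaks, and 181 of them were on chromosomes 6 and 8. The densest stretch ran from 3 to 8 Mb of chromosome 14 and held 3735 peaks, 66.2% of that chromosome's, among unnamed gene models. Other dense windows contained the Zfp and Rex2 genes of chromosome 4 (612 peaks from 147000001 to 148000000), the Sp110 and Sp100 genes of chromosome 1 (482) and the Klra natural killer receptor genes of chromosome 6 (367). Not every dense window held a gene family. On chromosome 17, 486 peaks with a median fold of 2.0 lay from 30000001 to 31000000. The 6 protein-coding genes there were Zfand3, Btbd9, Glo1, Dnah8, Glp1r and Umodl1.

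The 5 strongest peaks over 1 kb from any boundary were 226 to 404 bp wide. Their −log10 q was 746 to 1110, where the median of the list was 3.31. The first, of fold 27.3, lay on chromosome 17 at 82988875 to 82989278, 25629 bp from the nearest gene, Gm4601. Peaks of 26.0 inside Cntnap5c (chromosome 17, 57855956 to 57856344) and 25.2 at 8363 bp from Rimbp3 (chromosome 16, 17222267 to 17222498) came next. A peak of 23.6 inside Gm46595 (chromosome 17, 70963662 to 70963887) and one of 22.8 inside Gphn, the gephyrin gene (chromosome 12, 78350887 to 78351151), completed the 5.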

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

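The tests of explanations in this part were all chosen after the results were seen.

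Some peaks lay outside the chromosomes compared. Unplaced and random scaffolds held 858 peaks on 29 scaffolds, with a median fold of 2.41 against 2.09 on the chromosomes, and 4 scaffolds assigned to chromosome 1 held 635 of them. The mitochondrial genome held 2 peaks, with folds of 1.12 and 2.06. These were singled out because they carry signal in sequence that no comparison used.

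Chromosomes 6 and 8 together had 57.6 peaks per Mb against 18.7 on the other autosomes. A few repeat blocks are argued against, since the median 1 Mb window held 4.5 times as many peaks (45 against 10), and so is binding at gene ends alone, since the density over 10 kb from any protein-coding boundary was 2.94 times higher. Extra copies of both chromosomes in these cells remain a candidate explanation, which these values cannot single out. Of their windows, 91.4% lay above the median window of the other autosomes, where the highest of those autosomes reached 57.0%. Both chromosomes were picked for their many peaks, and any cause acting along whole chromosomes would give such a share. Chromosome X, with 31.0% of windows above that median, lay on the other side. Copy number was not measured, and the excess in occupied genes was 3.09-fold for all peaks, 3.07-fold at a fold of at least 2.5 and 1.6-fold at a fold of at least 5, where 1.01% of genes against 0.633% were occupied.

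The 2-cell-state list was occupied in 64.7%. Dense surroundings alone are argued against by the lists matched on surrounding peaks (45.9%, adjusted permutation p = 0.0277), although those lists themselves stood above the 18.8% of other genes. That test counts copies in repeated families as separate genes, so its p-value can be too small. Reads shared between near-identical copies remain open: 29 of the 34 members belong to repeated families, and of the 5 others only Zfp352 and Tmem92 were occupied (40%, Fisher exact p = 0.238). Binding at these genes and reads shared between copies therefore cannot be told apart in this list, because too few members stand alone.

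The run of peaks over Nelfa was a further pattern. Copies of the Nelfa coding sequence alone would leave the neighbouring sequence bare. In the 10 kb beyond the lower-coordinate end lay 6 peaks, above the 95th percentile of 3 at genes of similar length. Their folds were 2.04 to 2.63, where the highest inside the gene was 17.2. They were part of the pattern that prompted the question, so their count is no separate test. It does not address the peaks inside the gene. Reads from a construct that includes genomic sequence and a broad signal over the native gene both stay open and were not tested.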

How the results depend on the processing

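No paired analysis was possible because the one peak list carries no value per library and no replicate number. Of 218 comparisons of a result with an alternative, 138 planned beforehand and 80 added after the data were seen, 177 tested values kept direction and side of the threshold, 6 passed it only under the alternative, 8 passed it only in the main setting and 4 reversed direction, 2 of them with no call in either setting. Of the counts, 20 stayed within 1.5 times the main count and 3 moved further. The boundary share, the share within genes, the side of the summit, spacing, chromosome X, long non-coding RNA and the 2-cell-state list kept both under every alternative among these comparisons. For the 2-cell-state list, they count copies in repeated families as separate genes. Its 5 members outside such families were tested apart from these comparisons and gave no call (40%, Fisher exact p = 0.238). The share between genes reversed outside densely covered windows (55.9%, above 51.2% in placements) and with protein-coding boundaries (61.5%, above 59.5%), and lost its call without chromosomes 6 and 8 (50.3%). Without a call, proteasome genes reversed at a −log10 q of at least 4 (7.69%, odds ratio 0.766, against 1.49 in the main setting) and lineage transcription factor genes with a 2 kb window (23.1%, 1.08, against 0.562). The strength difference outside densely covered windows was 0.0112 on the log2 scale, past no threshold. Pluripotency genes lost their call with a 2 kb window (38.5%, odds ratio 2.25), outside densely covered windows (30%, 2.74) and without chromosomes 6 and 8 (27.3%, 2.07), against an odds ratio of 2.7 in the main setting. Glycolysis genes passed only under 4 alternatives and immediate early genes only under 2. Occupied protein-coding genes, 4120 in the main setting, numbered 2722 at or above the median fold, 2147 at a −log10 q of at least 4 and 2345 outside densely covered windows, where fewer peaks or genes enter, and 3030 to 4765 under the others. Lists occupied more often numbered 8 to 10, against 9 in the main setting. Apart from that, the cause was not tested. One row per interval changes nothing, since no interval repeats. Alternatives that need sequence or strand (CpG-matched lists, lists without repeated promoter sequences, opposite-strand start sites, and those of CpG promoters and motifs) were not run, and histone genes had no member outside densely covered windows. The unknown read depth limits what an absent peak can mean.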

Other observations

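The tests in this part were chosen after the data were seen, on families formed by the letters before the first digit of the gene symbol. Among 221 families of at least 12 protein-coding genes, 16 were occupied more often than lists matched on surrounding peaks and 9 less often (Benjamini-Hochberg adjusted p under the threshold of 0.05, 10000 lists). Subunit genes of the Integrator complex, which can end transcription of paused polymerase, were occupied in 11 of 15 cases (73.3%, adjusted permutation p = 0.00442), with folds of 3.77 at Ints13 and 3.31 at Ints6 and no summit in the control windows. Krüppel-like factor genes were occupied in 12 of 17 cases (70.6%, adjusted permutation p = 0.00442), and the Lsm genes of RNA processing in 9 of 13 (69.2%, adjusted permutation p = 0.0068). Genes with the prefix Eif, used for translation initiation factors, were occupied in 25 of 56 cases (44.6%, adjusted permutation p = 0.00442). Those with the prefix Eef, used for elongation factors, were occupied in 8 of 15 (53.3%, adjusted permutation p = 0.0354), with Eef1a1 at 5.08. The prefix alone placed a gene in its family, so not every member need be such a factor. General transcription factor genes (Gtf) reached 11 of 23 (47.8%) and TBP-associated factor genes (Taf) 11 of 24 (45.8%). At the low end, none of 56 keratin-associated protein genes and none of 40 secretoglobin genes was occupied, and 5 of 99 cytochrome P450 genes were (5.05%).

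Within the NELF complex, Nelfa had boundary peaks, but reads from the NELFA transgene cannot be separated from those of this gene. The other subunit genes Nelfb, Nelfcd and Nelfe had 0 boundary peaks. Pou5f1, the core pluripotency gene, and Myc had 0 as well, and Sox2 had 1, of fold 2.41. These genes were chosen after their values were seen.

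The highest −log10 q values did not go with the highest folds. The first, 161181 at chromosome 2 from 98666256 to 98667365, had a fold of 7.38, and 9 of the 15 highest lay on chromosome 9 below 3.1 Mb, with folds of the 15 between 4.41 and 9.85. Regions of unusually high signal were not left out, and whether these 15 peaks lie in such regions was not tested. Their −log10 q alone therefore does not mark them as the surest sites of the tagged protein.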
